A study of Mus musculus with 12 samples.

How the data were processed

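Total RNA from sorted CD4 intraepithelial T lymphocytes of the mouse small intestine was measured on 12 Illumina MouseRef-8 BeadArrays. Per the labels' protocols, RNA was extracted with Trizol, cleaned with a column kit and treated with DNase, and biotinylated cRNA was made with a nano-scale amplification kit. The authors deposited a table of mean bead intensity per probe, exported from GenomeStudio 1.0.6 with no normalization, per the file headers. The same deposited table gives a detection score for each probe, which runs from 0 to 1 and rises with signal, and was read as 1 minus a detection p-value. It also gives the number of beads per probe. A deposited table of log2 values came with no stated scale or centring. Set against the intensity table, it was found to hold log2 raw signals shifted by a constant per array and then centred for each probe on the median of the 3 arrays of 1 host and replicate. That median was 0 in 100% of the rows within a tolerance of 1e-06, and the median of each column was 0. The direction of these values was the same as that of the intensities.

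The labels name 6 groups of 2 arrays, which are 3 sorted subsets in 2 kinds of host. The deposited tables conflict on the host of replicate 1. Within each set of 3 arrays from 1 host and replicate, differences between arrays were compared across tables. The 2 sets of replicate 2 were equal under the same label, and the 2 sets of replicate 1 were equal only under the other host's label, with a tolerance of 1e-05 on the log2 scale. Sets that were not equal differed by 1.2 or more at their largest. No array was moved to another group. The host names used below are those of the intensity table, and a result that depends on the host is also given with the hosts of replicate 1 exchanged.

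Intensities were processed in R 4.3.3 with limma 3.58.1. Background was corrected by neqc, which inferred the negative-control level from the detection p-values, with an offset of 16, followed by quantile normalization and log2. Of 25697 probes, 14635 were detected at p under 0.05 on at least 2 arrays and were kept. Gene symbols are those of the table. Of the probes, 20736 carried a current symbol of the GRCm38.p6 reference gene table and 3841 an older symbol that it maps to a current gene, while 1120 kept the name in the file. The probe with the highest mean over all arrays stood for each gene, which left 10612 genes. No coordinates are printed because the tables name no genome build.

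Before the data were examined, 12 comparisons were fixed, each tested by limma on all 12 arrays with 6 group means and no block, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. This fit had 6 residual degrees of freedom. After the data were seen, 3 comparisons of the subsets over both hosts were added, since they do not depend on the host of replicate 1. They were fitted by limma on all 12 arrays with the 4 sets of 3 arrays as a block, which also left 6 residual degrees of freedom. Whether replicate numbers mark shared conditions was checked by correlating the differences between replicates 1 and 2 across genes. In all 15 pairs of groups the correlation was above 0.1, from 0.356 to 0.657, so the numbers were taken as pairing the samples from the data, since the labels name no shared day or animal. Nothing in the labels says that the replicates came from separate animals, and p-values then measure only the spread between these samples, which may be technical.

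Named genes were chosen by a rule fixed beforehand. The sorting genes came first, then, for the CD8a+ against ThPOK+ comparisons, the 10 highest and 10 lowest called genes whose groups did not overlap, or 5 each way elsewhere, and up to 4 members of each list with the smallest p. The same rule was applied to the added comparisons. Not every gene that it names is reported here by itself, and all are included in the counts and list tests. Of 24 fixed gene lists, 23 had at least 5 measured genes and were tested with camera at a preset inter-gene correlation of 0.01, and again with an estimated correlation. The lists were CD4 helper lineage, CD8 lineage and cytotoxic regulators, cytotoxic effectors, NK-type receptors and adaptors, gut intraepithelial residence, naive and circulating T cell, regulatory T cell, Th17, Th1, Th2, follicular helper T cell, inhibitory receptors, TGF-beta signalling, T cell receptor complex and proximal signalling, interferon response, proliferation, immediate early and stress, ribosomal proteins, and markers of epithelium, Paneth and goblet cells, B and plasma cells, myeloid cells, gamma-delta and CD8ab T cells, and erythroid cells.

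A called gene detected on 0 or 1 array of the dimmer subset is given as a bound. It sets the brighter mean against the mean over the dimmer arrays, where an array without detection takes the higher of its lowest detected signal and the probe's own signal. The fits were tested on simulated data for 10612 genes, of which 200 were changed. For the CD8a+ against ThPOK+ comparison over both hosts, 46.3% of genes changed by 1 on the log2 scale were recovered, 97.0% of those changed by 2 and 100% of those changed by 3. For the WT CD8a+ against ThPOK+ comparison without a block, the shares were 0%, 8.96% and 53.0%, and with the replicate number as a block they were 1.49%, 56.7% and 83.3%.

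Alternatives covered the background correction, the scaling, the detection filter, testing of every probe, array weights, a variance trend, the arrays in the fit, the replicate block, and each array left out in turn. Added after the data were seen were the exchanged hosts, the authors' log2 values with a block, the sets of each replicate number alone, and Paneth and epithelial covariates. Chip position as a block was not run, because the columns do not name it, and the authors' log2 values were not fitted without a block, because their centring would give wrong degrees of freedom. The number of arrays limits the precision.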

Results

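Small-intestinal intraepithelial CD4 T cells were profiled to ask how cells that have lost the helper-lineage transcription factor ThPOK, and acquired CD8a, differ from those that keep ThPOK. ThPOK was followed by a green fluorescent protein reporter, and cells were sorted into ThPOK+CD8a-, ThPOK-CD8a- and ThPOK-CD8a+ subsets, called here ThPOK+, CD8a- and CD8a+ cells. They came from reporter mice (labelled WT) or from lymphocyte-deficient RAG-/- recipients that had received naive CD4 T cells of reporter mice as a colitis model (labelled TR). The mice were 10 to 12 weeks old. Each of the 6 groups had 2 arrays, replicates 1 and 2.

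The replicate numbers separated the arrays. The median raw signal was 113.6 to 130.8 on the 6 arrays of replicate 1 and 206.7 to 246.2 on those of replicate 2. Between 12024 and 13091 probes were detected on each array of replicate 1, and between 6721 and 8195 on each array of replicate 2. Both replicate numbers hold all 6 groups. The correlation across genes between the replicates of a group was 0.806 to 0.906. The deposited tables name opposite hosts for the arrays of replicate 1, so comparisons of subsets over both hosts, which hold whichever table is right, are given before those within or between hosts.

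Transcripts of the sorting markers did not separate the subsets and so gave no check of the sort. Cd8a was detected on 12 of 12 arrays, with a mean log2 signal of 7.53 ± 0.36 (SD, n = 4) in ThPOK+ cells, 7.82 ± 0.42 in CD8a- cells and 7.97 ± 0.45 in CD8a+ cells. The difference between CD8a+ and ThPOK+ cells, 0.43 ± 0.21 (SE), was not past the threshold (limma, adjusted p = 0.543). Cd4 was detected on 12 of 12 arrays at 10.48 ± 0.53, 10.69 ± 0.10 and 10.59 ± 0.11 in the same order. Runx3, which encodes a transcription factor of the CD8 lineage, was detected on 0 of 12 arrays. No probe carried the symbol Zbtb7b, the gene of ThPOK. A probe named Zfp67, an older symbol shared by 2 genes, was detected on 4 of 12 arrays and does not check the sort.

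In CD8a+ cells, genes of the Th17 program and of helper T cells were lower than in ThPOK+ cells and genes of cytotoxic cells were higher. Over both hosts, 27 genes rose and 33 fell (limma with the set of arrays as a block, adjusted p under 0.05, n = 4 per subset), all 60 in the same direction in 4 of 4 sets. The genes were called on these same 4 sets, so the shared direction is no separate test. The Th17 list fell by a mean of 2.15 on the log2 scale (camera adjusted p = 2.12e-18 with the preset correlation, and 0.0239 with an estimated correlation). Of its 12 measured members, 7 were past the threshold over all genes and 10 when adjusted over the list alone. Ccr6, a chemokine receptor of Th17 cells, fell by 3.68 ± 0.35 (SE), from a log2 signal of 10.52 ± 0.40 (SD) to 6.83 ± 0.71. Il17a, the signature cytokine, was detected on 1 of 4 arrays of CD8a+ cells and was at least 6.78-fold higher in ThPOK+ cells (adjusted p = 0.0108). Il1r1, the interleukin-1 receptor gene, fell by 2.77 ± 0.26. Il22 was detected on 0 of 4 arrays of CD8a+ cells and was at least 3.43-fold higher in ThPOK+ cells (adjusted p = 0.0123).

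**Figure D1:**
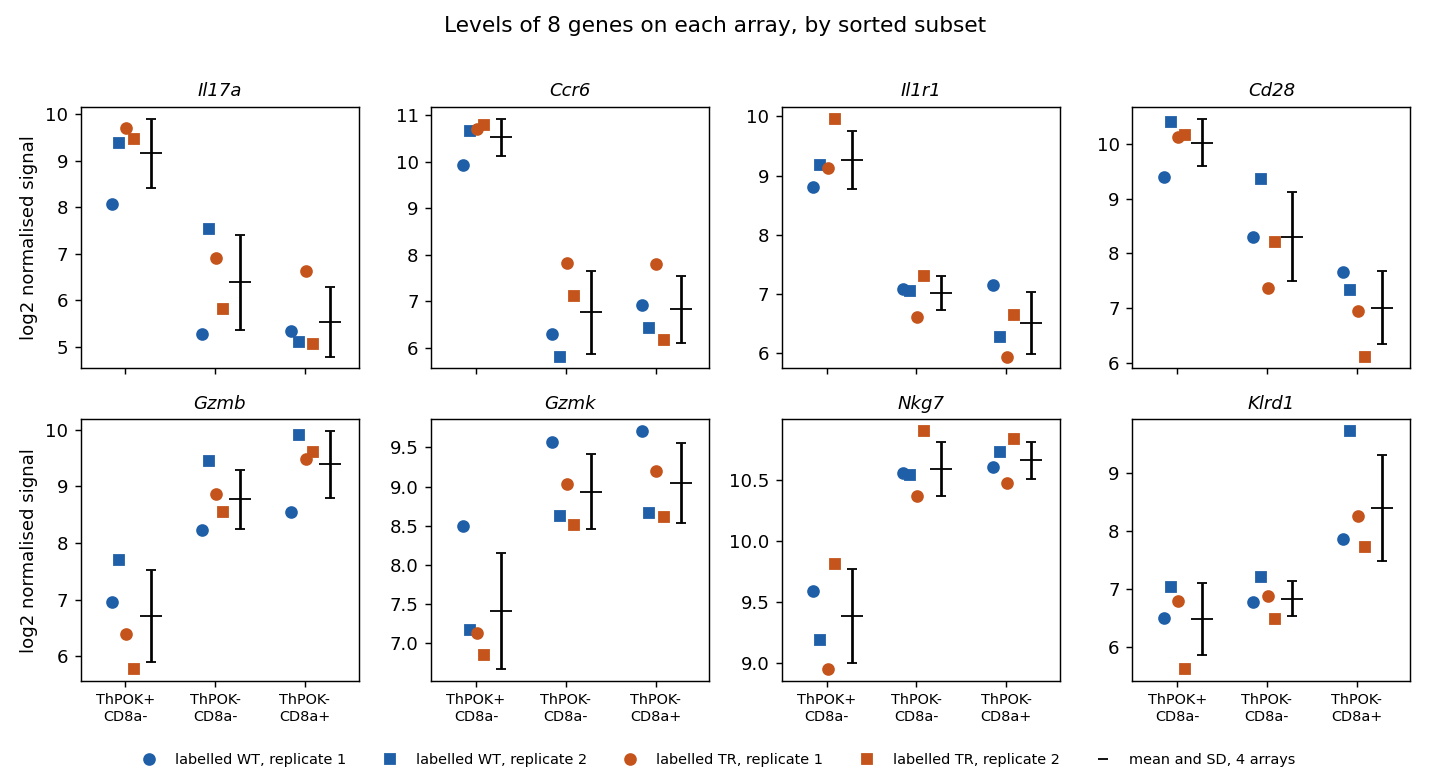
Log2 normalised signal of 8 genes on each of the 12 arrays, by sorted subset, with the mean and SD of 4 arrays beside the points, colour for the labelled host and shape for the replicate number. Il17a, Ccr6, Il1r1 and Cd28 are highest in ThPOK+ cells, with Il17a at a mean of 9.15 there and 5.53 in CD8a+ cells, where it was detected on 1 of 4 arrays. Gzmb, Gzmk and Nkg7 are higher in both ThPOK-negative subsets than in ThPOK+ cells, and Klrd1 is highest in CD8a+ cells.

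The CD4 helper lineage list fell by a mean of 1.61 (adjusted p = 5.22e-11), with 4 of 8 measured members past the threshold over all genes and 6 adjusted over the list alone. These were the costimulatory receptors Cd28 (fell by 3.01 ± 0.38) and Icos (fell by 2.05 ± 0.22), the CD40 ligand gene Cd40lg (fell by 1.17 ± 0.17) and the transcription factor gene Tcf7 (fell by 2.18 ± 0.38). The regulatory T cell list shifted by -0.63 (adjusted p = 1.13e-06), or by -0.34 with the naive and circulating mean as a covariate (adjusted p = 0.00332). Of its 13 members Tnfrsf4, which encodes the receptor OX40, was detected on 1 of 4 arrays of CD8a+ cells and was at least 2.59-fold higher in ThPOK+ cells, while Swap70 rose by 2.05 ± 0.24. The Th2 list shifted by -0.74 (adjusted p = 9.57e-05) with 0 of 7 members past the threshold over all genes and 3 adjusted over the list alone. The interferon response list shifted by -0.22 (adjusted p = 0.00448) with 0 of 25 members past it. With the naive and circulating mean as a covariate it was at -0.148 and not called (adjusted p = 0.073). All of these list calls held with an estimated correlation. The naive and circulating T cell list shifted by -1.09 (adjusted p = 1.18e-07), but its adjusted p was 0.166 with an estimated correlation, and Tcf7 alone of 14 members was past the threshold. The 4 sets ran from -2.21 (TR replicate 1) to -0.15 (WT replicate 1). The follicular helper list shifted by -0.76 (adjusted p = 0.00774, and 0.166 with an estimated correlation), and Icos alone of 8 members fell.

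The cytotoxic effector list rose by a mean of 0.66 (adjusted p = 4.39e-08, and 0.0256 with an estimated correlation), with 4 of 16 measured members past the threshold over all genes and 8 adjusted over the list alone. Gzmb, the gene of granzyme B, rose by 2.69 ± 0.32, from 6.70 ± 0.82 to 9.39 ± 0.59. Gzmk, another granzyme gene, rose by 1.64 ± 0.17, Nkg7, which encodes a membrane protein of cytotoxic granules, by 1.28 ± 0.16, and Fasl, the Fas ligand gene, by 1.20 ± 0.20. The list of NK-type receptors rose by 0.64 (adjusted p = 9.36e-06), with 2 of 14 members past the threshold, Klrd1 (the CD94 chain, 1.90 ± 0.26) and Cd244a (the receptor 2B4, 2.51 ± 0.35). The CD8 lineage list rose by 0.66 (adjusted p = 0.000107), with Cd244a as the only 1 of 11 members past the threshold and 6 higher and 1 lower when adjusted over the list alone. Cd160 in that list differed by 1.06 ± 0.19 (adjusted p = 0.0522). The CD8 lineage list also holds cytotoxic regulators and shares Cd244a, Cd160 and Crtam with the NK-type list, so the 2 rises are not separate results. Of its lineage genes, Runx3 was detected on 0 of 12 arrays and Cd8a was not past the threshold. The gut intraepithelial residence list rose by 0.41 (adjusted p = 4e-04). Litaf rose by 1.38 ± 0.21, and Itgae, which encodes the integrin chain CD103, differed by 1.17 ± 0.22 (adjusted p = 0.0614). These 3 list calls also held with an estimated correlation.

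Outside the lists, Mras, a small GTPase gene, and Scin, the gene of an actin-severing protein, were detected on 4 of 4 arrays of CD8a+ cells and 0 of 4 of ThPOK+ cells. Mras was at least 6.80-fold higher (adjusted p = 0.0123) and Scin at least 4.26-fold higher (adjusted p = 0.0483). Lat2, an adaptor gene, rose by 2.83 ± 0.35, OTTMUSG00000000990 by 2.50 ± 0.31, and Nr4a2, a nuclear receptor gene of the immediate early list, by 1.99 ± 0.24. Glp1r, the glucagon-like peptide 1 receptor gene, was 6.06-fold higher (adjusted p = 0.0279). Among the largest falls were LOC100048845 (fell by 3.67 ± 0.49) and, from the Th17 list, Tmem176b (fell by 2.57 ± 0.33) and Tmem176a (fell by 2.46 ± 0.39). The sialyltransferase gene St6gal1, detected on 1 of 4 arrays of CD8a+ cells, was at least 4.70-fold higher in ThPOK+ cells, and Apbb1, detected on 1 of 4 arrays of ThPOK+ cells, was at least 2.88-fold higher in CD8a+ cells. The Th1 list had a mean shift of 0.015 and was not called, although Ccl4, a chemokine gene, rose by 1.92 ± 0.27. Adjusted over the list alone, 5 of its 12 measured members were higher and 4 lower, so the mean hides opposite shifts. The lists of inhibitory receptors, TGF-beta signalling, the T cell receptor complex and proliferation were not called, with mean shifts of 0.21, 0.013, 0.013 and 0.011. In the inhibitory receptor list, 4 of 11 members were higher and 3 lower when adjusted over the list alone. The median of the TGF-beta list was -0.069, opposite in sign to its mean. The immediate early and stress list shifted by -0.12 (adjusted p = 0.0224, and 0.166 with an estimated correlation) and the ribosomal protein list by -0.13 (adjusted p = 0.00448, and 0.429 with an estimated correlation).

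**Figure D2:**
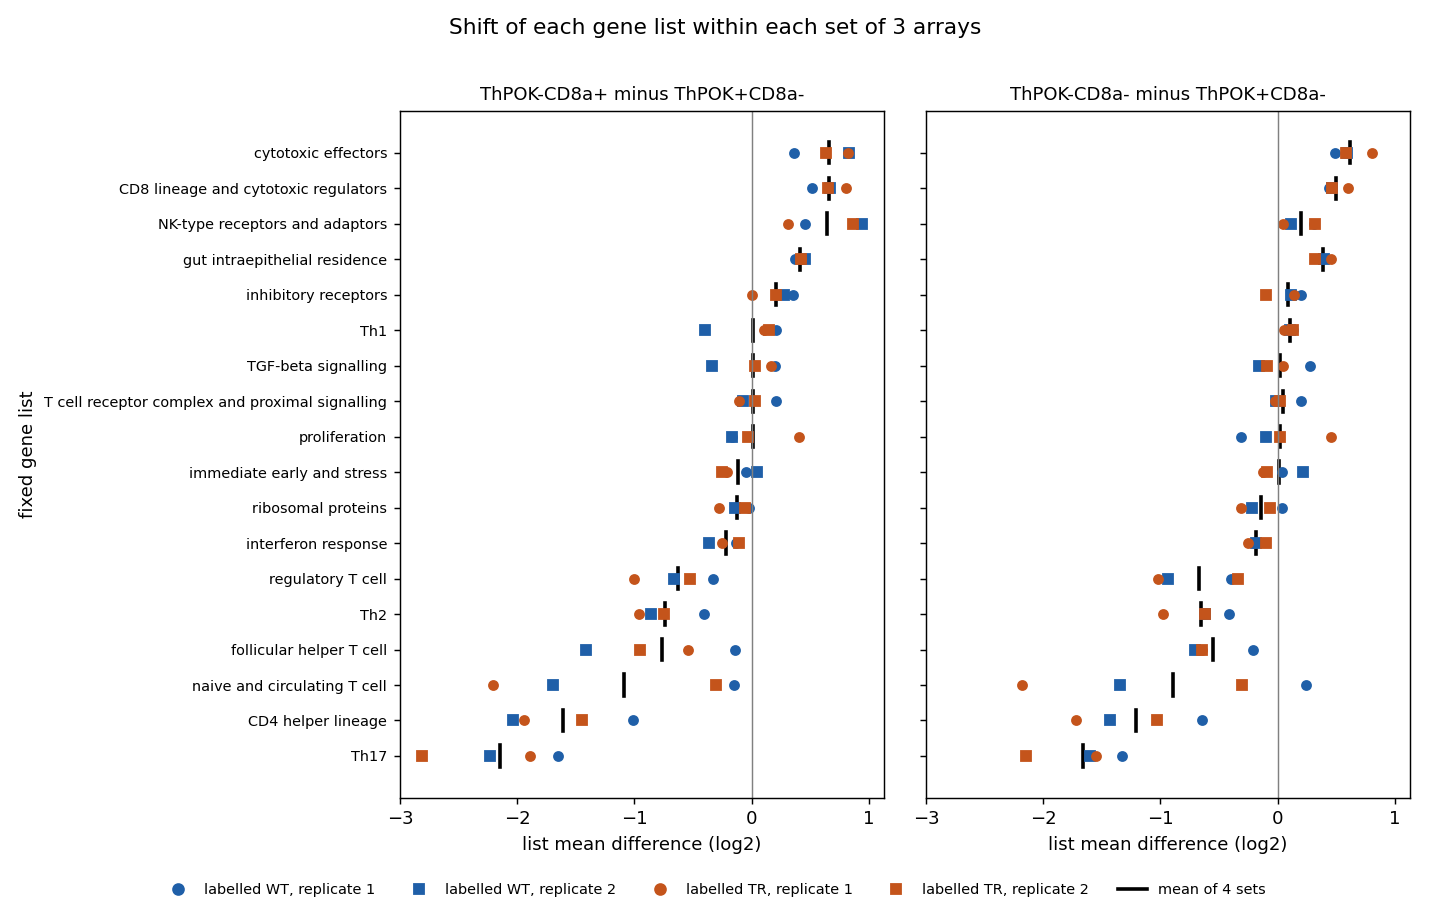
Difference of the mean log2 signal of each fixed gene list from ThPOK+ cells, for CD8a+ cells on the left and CD8a- cells on the right, with 1 point per set of 3 arrays and a bar at the mean of 4 sets. In CD8a+ cells the Th17 list lies between -2.813 and -1.651 in the 4 sets and the cytotoxic effector list between 0.359 and 0.827.

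Markers of gut epithelium also differed between arrays. The Paneth and goblet list, genes of secretory epithelial cells, shifted by -0.85 in CD8a+ against ThPOK+ cells (adjusted p = 0.0086, and 0.5 with an estimated correlation; -0.225 without WT ThPOK+ replicate 1, -0.509 without WT CD8a+ replicate 1, -0.521 without TR CD8a+ replicate 1 and -0.732 without TR CD8a+ replicate 2, none of them called), alongside the Th17 and helper lists, while the epithelium list shifted by -0.31 and was not called. The mean log2 signal of the Paneth and goblet list was 9.54 and 8.50 on the arrays of WT ThPOK+ replicates 1 and 2 and 10.15 on that of WT CD8a+ replicate 2. It was 5.40 to 7.25 on the other 9 arrays. The sets went opposite ways. Between CD8a+ and ThPOK+ cells this list differed by -1.847 and -0.415 in the sets of TR replicates 1 and 2. It differed by -2.796 and 1.646 in those of WT replicates 1 and 2. The epithelium list differed by -0.586, -0.204, -2.211 and 1.78 in the same order. Lists of B and plasma, myeloid and erythroid cells shifted by -0.074, -0.12 and -0.24 and were not called, and the median of the B and plasma list, 0.0060, was opposite in sign to its mean. The gamma-delta and CD8ab T cell list had 3 measured genes, a mean shift of 0.21 and no set test. The count of 60 genes was 17 without WT ThPOK+ replicate 2, 39 without WT CD8a- replicate 1, 26 without WT CD8a+ replicate 2, 2 without TR ThPOK+ replicate 1, 32 without TR ThPOK+ replicate 2, 29 without TR CD8a- replicate 1, 30 without TR CD8a- replicate 2, 5 without TR CD8a+ replicate 1 and 17 without TR CD8a+ replicate 2. It was 0 with only the 8 arrays compared in the fit, 29 with the replicate number alone as a block and 19 with no block.

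**Figure D3:**
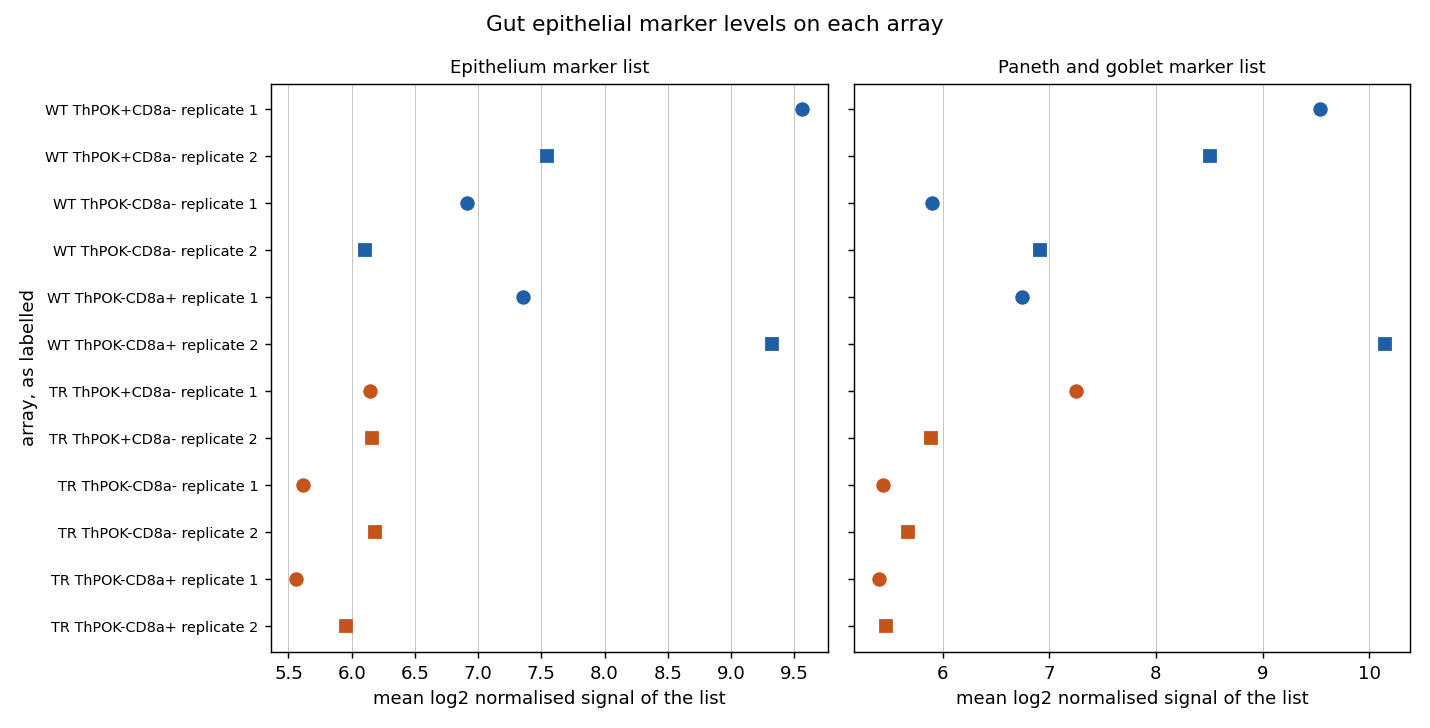
Mean log2 normalised signal of the epithelium list and of the Paneth and goblet list on each of the 12 arrays, with colour for the labelled host and shape for the replicate number. The Paneth and goblet list reaches 10.15 on the array of WT CD8a+ replicate 2 and 9.54 on that of WT ThPOK+ replicate 1.

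ThPOK-negative cells without CD8a shifted in the same directions. Against ThPOK+ cells, 3 genes rose and 3 fell in CD8a- cells over both hosts. Ccr6 fell by 3.75 ± 0.35 (limma adjusted p = 0.0187), and Il1r1 by 2.25 ± 0.26. Tnfrsf4, detected on 1 of 4 arrays of CD8a- cells, was at least 2.53-fold higher in ThPOK+ cells, while Gabarapl1, an autophagy gene, rose by 1.67 ± 0.18, Gzmk by 1.52 ± 0.17 and Nkg7 by 1.21 ± 0.16. All 6 were also among the 60 of CD8a+ cells, where independent lists would share 0.0076 rising and 0.0093 falling genes. Both comparisons use the same ThPOK+ arrays. Their fold changes correlated across genes at 0.670, against 0.498 in simulated arrays without effects, with a covariance of 0.109 against 0.0391. When the sets were split so that no ThPOK+ array was shared, the correlation was 0.251 and the covariance 0.0629. Genes are not independent replicates.

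The Th17 list fell by a mean of 1.66 in CD8a- cells (camera adjusted p = 4.42e-14), the CD4 helper list by 1.21 (adjusted p = 3.04e-09), the regulatory T cell list by 0.67 (adjusted p = 1.01e-07) and the Th2 list by 0.66 (adjusted p = 7.72e-05). The cytotoxic effector list rose by 0.62 (adjusted p = 5.92e-09) and the gut residence list by 0.39 (adjusted p = 7.72e-05). These 6 calls held with an estimated correlation. The CD8 lineage list shifted by 0.49 (adjusted p = 0.0033, and 0.0529 with an estimated correlation) and the interferon list by -0.18 (adjusted p = 0.0169, and 0.0925 with an estimated correlation). The naive list shifted by -0.90 (adjusted p = 4.32e-07, and 0.214 with an estimated correlation), with the 4 sets at -2.178 and -0.304 for TR replicates 1 and 2 and 0.239 and -1.345 for WT replicates 1 and 2. Its signal was highest on the arrays of TR ThPOK+ replicate 1 (9.12) and WT ThPOK+ replicate 2 (8.48). The follicular helper list shifted by -0.55 (adjusted p = 0.0118, and 0.214 with an estimated correlation) and the ribosomal list by -0.14 (adjusted p = 0.000411, and 0.3 with an estimated correlation). The epithelium and the Paneth and goblet lists shifted alongside by -1.15 and -1.81, with an adjusted p of 3.48e-08 and 7.19e-08, and of 0.319 and 0.214 with an estimated correlation. The NK-type receptor list had a mean shift of 0.19 and was not called. It was called with the Paneth and goblet covariate (0.378, camera adjusted p = 0.013) and with the epithelium covariate (0.316, adjusted p = 0.0197). With the naive and circulating covariate it was not called (0.277, adjusted p = 0.0593). Lists of inhibitory receptors and of immediate early genes were not called either, with means of 0.086 and 0.0094 and medians of the opposite sign, -0.19 and -0.061. Adjusted over the list alone, 3 of 11 inhibitory receptor genes were higher and 2 lower. The count of 6 genes was 0 with only the arrays compared in the fit, 3 with no block, all of them lower, and 0 with the Paneth and goblet covariate. It ranged from 0 to 14 when 1 array was left out. It was 14 without WT ThPOK+ replicate 1, 12 without WT CD8a+ replicate 2, 2 without WT CD8a- replicate 2, 1 without TR ThPOK+ replicate 1 or TR CD8a+ replicate 2, and 0 without WT ThPOK+ replicate 2, WT CD8a- replicate 1, TR ThPOK+ replicate 2, TR CD8a- replicate 1, TR CD8a- replicate 2 or TR CD8a+ replicate 1.

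Between the ThPOK-negative subsets, no gene passed the threshold and no list was called with an estimated correlation. In CD8a+ against CD8a- cells, limma called 0 of 10612 genes, and 541 had an unadjusted p under 0.05. The NK-type receptor list shifted by 0.45 (adjusted p = 0.000192, and 0.25 with an estimated correlation), with Klrd1 at 1.56 ± 0.26 (adjusted p = 0.895). The gamma-delta and CD8ab T cell list, with 3 measured genes and no set test, moved with it at a mean of 0.50, from 0.105 to 1.172 in the 4 sets, and both lists were highest in the set of WT replicate 2. The Th17 list shifted by -0.49 (adjusted p = 0.000697, and 0.531 with an estimated correlation). The CD4 helper list shifted by -0.40 (adjusted p = 0.0172, and 0.595 with an estimated correlation), with Cd28 at -1.29 ± 0.38. The epithelium list shifted by 0.84 and the Paneth and goblet list by 0.96, with an adjusted p of 3.57e-06 and 0.00248, and of 0.891 for both with an estimated correlation. The 4 sets ran from -0.229 to 3.22 and from -0.202 to 3.241, both highest in that of WT replicate 2, and without WT CD8a+ replicate 2 the shifts were 0.101 and 0.165 (adjusted p = 0.963 and 0.964). The Paneth and goblet call was also lost without WT CD8a- replicate 1 (0.677) or replicate 2 (0.618). The CD4 helper call was lost without WT CD8a- replicate 1 (-0.315), WT CD8a+ replicate 2 (-0.297), TR CD8a- replicate 2 (-0.370) or TR CD8a+ replicate 1 (-0.376). It was also lost with the Paneth and goblet covariate (-0.276, camera adjusted p = 0.12) or the epithelium covariate (-0.256, adjusted p = 0.125).

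Within each host, where 2 arrays stood against 2, the Th17 list was lower in CD8a+ than in ThPOK+ cells and no gene passed the threshold. In cells labelled WT, the Th17 list fell by a mean of 1.94 in CD8a+ against ThPOK+ cells (camera adjusted p = 1.9e-12) and the cytotoxic effector list shifted by 0.59 (adjusted p = 0.000236, and 0.0862 with an estimated correlation), or by 0.352 without WT ThPOK+ replicate 2 (adjusted p = 0.0596). In cells labelled TR, the Th17 list fell by 2.35 (adjusted p = 7.51e-22) and the cytotoxic effector list rose by 0.73 (adjusted p = 5.87e-07, and 0.037 with an estimated correlation). The naive, epithelium, and Paneth and goblet lists were among the 15 lists called under the TR label with the preset correlation. In the sets of TR replicates 1 and 2 they shifted by -2.21 and -0.301, -0.586 and -0.204, and -1.847 and -0.415. In those of WT replicates 1 and 2 they shifted by -0.15 and -1.697, -2.211 and 1.78, and -2.796 and 1.646. The difference between the hosts in the cytotoxic shift was 0.14 as TR minus WT and was not called (adjusted p = 0.553), and with the hosts of replicate 1 exchanged it was -0.33 (adjusted p = 0.0515). With that exchange the Th17 list shifted by -2.06 in WT and -2.23 in TR cells, and the cytotoxic list by 0.82 and 0.50. Gzmb differed by 1.90 ± 0.56 under the WT label (adjusted p = 1) and by 3.47 ± 0.56 under the TR label (adjusted p = 0.286). With the hosts exchanged Gzmb differed by 2.66 ± 0.58 (adjusted p = 0.23) in WT and 2.71 ± 0.58 (adjusted p = 0.777) in TR cells. Limma called 0 genes in all 6 subset comparisons within hosts. At an unadjusted p under 0.05 there were 375 genes for CD8a+ against ThPOK+, 349 for CD8a- against ThPOK+ and 423 for CD8a+ against CD8a- under the WT label, and 256, 155 and 33 under the TR label. With the hosts of replicate 1 exchanged and the replicate number as a block, the WT comparisons with ThPOK+ cells called 34 genes in CD8a+ cells and 4 in CD8a- cells. The replicate block within host called 1 gene for CD8a+ against ThPOK+ cells under the TR label.

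The fold changes between CD8a+ and ThPOK+ cells were compared between the hosts. Across 10612 genes, the fold changes under the WT and TR labels correlated with a Pearson r of 0.331 and a Spearman rho of 0.191, a covariance of 0.0840 and the same sign in 55.9% of genes. These comparisons share no array. With the hosts of replicate 1 exchanged, r was 0.248. It was 0.190 without WT CD8a+ replicate 1 and 0.204 without WT ThPOK+ replicate 2, the lowest values with 1 array left out. No overlap of calls could be tested, because neither host had any.

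Differences between the hosts depended on which table names replicate 1. Limma called 0 genes between TR and WT in each subset, and 218, 154 and 388 genes had an unadjusted p under 0.05 in ThPOK+, CD8a- and CD8a+ cells. The immediate early and stress list, genes of rapid cell activation, was called in all 3 subsets. It shifted by -0.43 in ThPOK+ cells (adjusted p = 0.0125), -0.66 in CD8a- cells (adjusted p = 2.94e-06) and -0.65 in CD8a+ cells (adjusted p = 0.000129), and by -0.53, -0.60 and -0.59 with the hosts exchanged. Its adjusted p with an estimated correlation was 0.711, 0.817 and 0.549 under the intensity table's naming, and 0.307, 0.278 and 0.58 with the hosts exchanged. Its mean log2 signal was 9.25, 9.46 and 9.29 on the ThPOK+, CD8a- and CD8a+ arrays of WT replicate 2 and 8.05 to 8.69 on the other 9. The exchange leaves replicate 2 as labelled, so the same direction under both namings is no separate test. The erythroid list moved with it under the intensity table's naming, by -1.30, -0.82 and -1.40 in the same order (adjusted p = 0.000517, 0.0295 and 0.00205, and 0.431, 0.817 and 0.546 with an estimated correlation), and was at -0.26, -0.39 and -0.37 and not called with the hosts exchanged. In CD8a- cells the epithelium and the Paneth and goblet lists shifted by -0.61 and -0.85 (adjusted p = 0.000473 and 0.0299, 0.00575 and 0.131 with the replicate block, and 0.817 for both with an estimated correlation), and were at 0.69 and -0.39 and not called with the hosts exchanged. In CD8a+ cells the epithelium list also shifted in the same direction under both namings, by -2.58 and -0.79. So did the Paneth and goblet list, by -3.01 and -1.67. With an estimated correlation the adjusted p was 0.284 for both lists under the intensity table's naming, and 0.674 and 0.58 with the hosts exchanged. Both namings keep WT CD8a+ replicate 2 under the WT label, and the Paneth and goblet mean on that array was 10.15. The same direction is no separate test here either. The proliferation list in CD8a- cells shifted by 0.34 (adjusted p = 0.00312) and, with the hosts exchanged, by -0.27 (adjusted p = 0.00303), and with an estimated correlation the adjusted p was 0.817 and 0.698. In ThPOK+ cells the epithelium list shifted by -2.40 under that naming and by 1.02 with the hosts exchanged, with an adjusted p of 0.265 and 0.497 with an estimated correlation. The Paneth and goblet list there shifted by -2.45 (adjusted p = 2.77e-16, and 0.272 with an estimated correlation) and was at -0.16 (adjusted p = 0.995) with the hosts exchanged. The naive list in ThPOK+ cells shifted by 0.42 (adjusted p = 0.193) under that naming and by -1.49 with the hosts exchanged (adjusted p = 4.73e-16, and 0.00788 with an estimated correlation). The regulatory T cell list there shifted by -0.050 (adjusted p = 0.722) and, with the hosts exchanged, by -0.90 (adjusted p = 9.34e-09, and 0.00788 with an estimated correlation). Median scaling in place of quantile normalization moved the median of all genes between hosts to 0.168, 0.144 and 0.124 in the 3 subsets.

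Whether a subset difference itself differed between the hosts was tested for each pair of subsets. Limma called 0 genes in all 3 tests, with 125 genes at an unadjusted p under 0.05 for CD8a+ against ThPOK+, 107 for CD8a- against ThPOK+ and 153 for CD8a+ against CD8a-.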

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

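The tests of Paneth and goblet RNA, of the replicate numbers and of the hosts of replicate 1 were chosen only after the results they concern were seen. The comparisons over both hosts were also chosen then.

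For the 60 genes that separated CD8a+ from ThPOK+ cells over both hosts, 1 of the 35 splits of these 8 arrays into 4 and 4, the real grouping, gave as many genes, and the highest of the others gave 1, but the 8 splits that part all 4 sets as the real one does are too few for a share under 0.05, with a highest other of 0. With the Paneth and goblet mean as a covariate, 55 of the 60 genes were still called among 97, which argues against RNA from those cells as the whole cause. With the naive and circulating list as a covariate the Th17 list still shifted by -2.211 (camera adjusted p = 2.75e-18), so its fall did not follow the level of the naive list. Of the 14 measured naive genes, 3 are in another list and 0 in the Th17 list. Naive cells in the ThPOK+ gate were thus not bound to raise the Th17 list there, and this result cannot weigh them as the source of its fall. With that covariate the CD4 helper list shifted by -1.146 and the regulatory T cell list by -0.340, against -1.61 and -0.63 without it. The interferon and follicular helper lists were then not called (adjusted p = 0.073 and 0.0503), so naive cells stay open as part of those shifts. The naive list shares Lef1 and Tcf7 with the CD4 helper list, so part of the smaller CD4 helper shift follows from this overlap. The Th17 list also shifted by -1.772 in the sets of replicate 1 alone and by -2.523 in those of replicate 2 alone. Its fall therefore does not rest on 1 replicate number. A change with the loss of ThPOK remains a hypothesis found and tested on the same data.

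For the 6 genes of CD8a- against ThPOK+ cells, 1 of the 35 splits, the real grouping, gave as many and the highest other gave 0, and here too the 8 splits that part all 4 sets are too few for a share under 0.05. With the Paneth and goblet mean as a covariate none of the 6 was called, while the shifts had a median ratio of 1.07 to those without it. Ccr6 was at -3.75 ± 0.35 (SE) before and -3.87 ± 0.48 after, with the call ended as the standard error widened (adjusted p = 0.0689, against 3.38e-06 to 0.943 over its alternatives other than leaving out 1 array). In the 6 genes the lower 95% limit of the shift with the covariate was 0.608 to 0.814 of the shift without it. The shift without it was taken as fixed, so its own error is left out. By a rule set after these values were seen, this argues against Paneth RNA as the whole cause of the shifts, and the calls themselves were not kept. The list's brightest genes, DEFA1, Itln1 and Defa21, had means of 10.4, 8.96 and 8.65 in ThPOK+ and 7.92, 6.59 and 6.57 in CD8a- cells, and 0 of its 12 measured genes are in another list.

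For CD8a+ against CD8a- cells the real count was 0 genes, which 35 of 35 splits reach by construction, so the splits test nothing there. The highest other gave 2.

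The host of the replicate 1 arrays stays open. If the hosts had been exchanged in the intensity table, the TR minus WT differences of replicates 1 and 2 would run against each other. They correlated across genes at 0.0527 in ThPOK+, -0.0713 in CD8a- and 0.146 in CD8a+ cells, with a median of 0.0527, and the tables cannot be told apart by this test because the subsets went different ways.

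Of 107 groups of 4 set differences, 6 held a set far from the other 3, where chance flags about 1 in 20. In the set of WT replicate 2, the Th1 list differed by -0.401 between CD8a+ and ThPOK+ cells and by -0.502 between CD8a+ and CD8a- cells. The CD8 lineage list differed by 0.603 between CD8a- and ThPOK+ cells in the set of TR replicate 1 and by 0.075 between CD8a+ and CD8a- cells in that of WT replicate 1. In the set of WT replicate 1, the follicular helper list differed by -0.209 between CD8a- and ThPOK+ cells, and the proliferation list by 0.145 between CD8a+ and CD8a- cells.

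Tests of the host difference picked out 7 list shifts, as TR minus WT, and none of them was called with an estimated correlation. The proliferation list differed by 0.353 for CD8a+ against ThPOK+ cells and by 0.441 for CD8a- against ThPOK+ cells, and with the hosts of replicate 1 exchanged by -0.217 and -0.326. The naive list differed by -0.688 for CD8a- against ThPOK+ cells, and by 1.73 with the hosts exchanged, with an adjusted p of 0.023, against 0.0714 with the replicate block and 9.78e-17 with the exchange. The epithelium list differed by 1.79 for CD8a- against ThPOK+ cells and by -1.97 for CD8a+ against CD8a- cells, and with the hosts exchanged by -0.325 (adjusted p = 0.354) and -1.48. The Paneth and goblet list differed by 1.60 and -2.16 in the same order, and with the hosts exchanged by -0.223 (adjusted p = 0.622) and -1.28 (adjusted p = 0.0795).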

How the results depend on the processing

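The alternatives that exchange the hosts of replicate 1, use the authors' log2 values, take the sets of 1 replicate number alone or add a covariate, and all alternatives of the comparisons over both hosts, were chosen after seeing the data. For CD8a+ against ThPOK+ cells over both hosts, the 60 genes became 134 without background correction, 119 with normexp, 113 under the stricter filter, 144 with a variance trend, 127 with the authors' values, 97 with the Paneth and 104 with the epithelium covariate. They became 29 with the replicate block alone, 19 with no replicate block, 0 with only the arrays compared in the fit, and 3 and 0 in the sets of replicates 1 and 2 alone, which have fewer arrays. Of the 3 genes in the sets of replicate 1, all lower, 0 were among the 60. Leaving out 1 array gave 2 to 78. For CD8a- against ThPOK+ cells, the 6 genes became 42 without background correction, 31 with median scaling (19 higher, 12 lower), 31 with normexp (20 higher, 11 lower), 32 under the stricter filter (22 higher, 10 lower), 41 with array weights, 58 with a variance trend (37 higher, 21 lower), 56 with the authors' values, and 0 and 11 with the Paneth and epithelium covariates. They became 3 with no replicate block, 0 with only the arrays compared, and 3 and 0 in the sets of replicates 1 and 2 alone, and leaving out 1 array gave 0 to 14. Here too, 0 of the 3 genes in the sets of replicate 1 were among the 6. For CD8a+ against CD8a- cells over both hosts, the settings run gave 0 genes. Within hosts, the counts of 0 became 76 (WT CD8a+ against ThPOK+), 33 (WT CD8a- against ThPOK+), 5 (TR CD8a+ against ThPOK+) and 1 (TR CD8a- against ThPOK+) with the authors' values and the replicate block within host. Exchanging the hosts of replicate 1 with the replicate block gave 34 and 4 for the WT comparisons with ThPOK+ cells, and the replicate block within host gave 1 for TR CD8a+ against ThPOK+. Leaving out background correction gave 1 for WT CD8a- against ThPOK+ and 1 for TR CD8a+ against ThPOK+. Leaving out 1 array gave 0 to 1 for WT CD8a+ against ThPOK+ and 0 to 4 for TR against WT in CD8a+ cells, where the lone array of a group is assumed to vary like the others. The replicate block changed no other gene count past its limit. The correlation of the hosts' fold changes, 0.331, became 0.438 under the stricter filter, 0.248 with the hosts exchanged, with or without the replicate block, and 0.190 to 0.331 with 1 array left out. Lists were followed over these settings only for the comparisons over both hosts and for CD8a+ against ThPOK+ cells within hosts. List shifts between hosts that turned with the exchange are given above and not counted here. Signs turned for the Paneth and goblet list over both hosts in the sets of replicate 2 alone (0.616). They turned for the WT follicular helper list without WT ThPOK+ replicate 2 (0.016, with -1.579 the lowest with 1 array left out). The TR proliferation list turned without TR CD8a+ replicate 1 (-0.198, with 0.573 the highest with 1 array left out), with the hosts exchanged (-0.098, with or without the replicate block) and with the authors' values (-0.044). For changes of setting that did not remove arrays or change labels, the cause was not tested. Of the other values, lists kept their direction and call in 553 results of alternatives and lost the call in 73, and with 1 array left out in 645 and 49. Named genes, called or not in the main fit, kept their call status in 4110 results, lost the call in 163 and gained it in 189. With 1 array left out these counts were 3192, 201 and 15. A turned sign was counted as kept where neither value passed the threshold. Only genes called in the main fit could lose a call, so the kept results are not the base for the losses. Chip as a block was not run, and the authors' values were not fitted without a block. Signal over background was lowest on the arrays of replicate 2, where 26.2% to 31.9% of probes were detected, against 46.8% to 50.9% on those of replicate 1.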

Other observations

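Markers of blood and B cells followed the replicate within the cells labelled WT. The erythroid list, which holds haemoglobin genes, had a mean log2 signal of 8.07, 7.67 and 7.84 on the ThPOK+, CD8a- and CD8a+ arrays of WT replicate 2, and 5.65 to 6.82 on the other 9 arrays. The B and plasma cell list was at 7.49, 6.92 and 7.44 on the same 3 arrays and at 6.01 to 6.49 on the other 9. The naive and circulating list was highest on the arrays of TR ThPOK+ replicate 1, at 9.12, and WT ThPOK+ replicate 2, at 8.48, and was 6.78 to 7.44 on the other 10.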
